A study of Mus musculus with 4 samples.

How the data were processed

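RNA was measured in 4 samples of sorted adult mouse bone marrow, 1 for each combination of 2 genotypes (WT littermates and SFRP5-transgenic mice) and 2 sorts (LSK and CLP). Per the labels' protocols, RNA was prepared with the RNeasy Micro kit from freshly isolated cells, and Cy3-labelled cDNA was made from 6.1 ng of total RNA with a whole-transcriptome amplification kit (Ovation Pico WTA System V2). The number of mice behind each sample, their sex and the transgene's sequence are not given in the sources used here. Per the file headers, the 4 arrays lie on 1 slide, were scanned once and carry probes annotated on mm9, so a slide batch does not separate the groups, whereas array position and group coincide.

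The deposited scanner files hold the intensity of each spot in 1 colour, background-subtracted and spatially detrended within the array by Agilent Feature Extraction 10.10.1.1 per the file headers (10.10 per the submitters' processing notes). The authors' deposited signal table holds that intensity times 1 factor per array (6.42 for WT LSK, 5.85 for SFRP5 LSK, 5.86 for WT CLP and 4.91 for SFRP5 CLP, computed here from the values). How the factors were set is not given in the sources used here. The authors' deposited ratio table holds the log2 of 1 array's scaled signal over another's, and differed from the log2 of the deposited signals by at most 0.019.

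The processed intensity of each of 59305 spots outside the controls was put on the log2 scale, and the 75th percentile of each array was subtracted. That percentile was 276.5 in WT LSK, 277.5 in SFRP5 LSK, 227.2 in WT CLP and 290.9 in SFRP5 CLP. Spots with an outlier flag (160, 133, 148 and 128 in the order WT LSK, SFRP5 LSK, WT CLP, SFRP5 CLP) were left out, and the other spots of a probe were averaged. No spot was saturated. Of 55681 probes, 33325 carried a gene symbol. Symbols were brought up to date through the Entrez IDs of 30994 probes found in the mouse RefSeq table (GRCm38.p6), which changed 3525 of them. That table was used for names alone, and no coordinates were taken from it. The probe with the highest mean signal stood for each of 24278 genes, and 18513 of these had a name that is not a clone or predicted name.

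A gene was measured in a comparison when its probe was well above background on both arrays, by the scanner software's own flag. A gene above background on 1 of the 2 arrays, with no probe of the gene above it on the other, was given a lower bound of its fold. The bound is taken against the lowest signal that passes the flag on the other array, or the gene's own signal there if that is higher. Each of 4 comparisons (SFRP5 minus WT in LSK and in CLP, and CLP minus LSK in WT and in SFRP5) is a difference of 2 log2 values, counted at 2-fold. With 1 array per group a comparison within a sort or within a genotype has no residual spread, so no p-value, standard error or adjusted value is given. A fit of genotype plus sort over the 4 arrays would leave 1 residual degree of freedom, but it assumes the same genotype difference in both sorts, and it was not run. The spread used here is that between replicate spots of 432 probes within an array, a median SD from 0.054 to 0.072 log2 above the 75th percentile and from 0.37 to 0.49 at the lowest signals. It covers neither cells, mice nor amplification.

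Before the data were examined, 48 gene lists were written down (pathways, cell types that the sorts hold or could hold, and quality markers), of which 1303 of 1340 entries were found on the array. A list's median difference, over members above background on at least 1 of the 2 arrays and with signals below background kept as measured, was set against the medians of 10000 random lists of the same size, matched in 20 bins of signal level. A list outside the 2.5th to 97.5th percentile is described as shifted. This compares a list with other genes of the same 2 arrays. If members varied independently, 2.4 of 48 lists would lie outside, against 13 above and 1 below for genotype in LSK, 12 and 7 in CLP, 15 and 7 between sorts in WT, and 14 and 11 in SFRP5. Genes that vary together between any 2 arrays would put more lists outside, so the excess does not measure an effect of genotype or sort. Neighbouring lists share members. Counts of members at 2-fold cover those above background on both arrays.

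The genes named in the text were chosen by a rule written before the data were examined, from symbols that are not clone or predicted names. For each genotype comparison it takes the 10 highest and 10 lowest differences among genes whose brighter array is at or above its 75th percentile, and the 5 highest and 5 lowest bounds. It also takes the 5 highest and 5 lowest in both sorts, the 10 highest and 10 lowest between sorts in both genotypes, and the 5 highest and 5 lowest differences between the genotype differences. From each list it takes the 2 highest and 2 lowest members per comparison, and all sort markers, sex-linked genes, haemoglobin genes and Sfrp5. Genes outside the rule are named as such.

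Alternatives fixed in advance were quantile normalization, cyclic loess, scaling by the median over probes above background on all arrays, normexp background correction with an offset of 50, the authors' signal table, no filter on dim probes, a filter for signal on all 4 arrays, the mean of a gene's probes, thresholds of 1.5-fold and 3-fold, the mean of a list, 10 level bins, and leaving out saturated probes. Normexp used the median spot signal, since the files hold no mean signal column. Chosen after seeing the data were a restriction to genes whose brighter array is at or above its 75th percentile, lists restricted to members above background on both arrays, lists without the genes shared with the immediate early list, the share of calls repeated by a gene's further probes, and the annotation's KEGG pathways with 15 to 300 genes. The fold counts and list percentiles were tested on simulated data, built from the mean of the 2 arrays of a comparison with the spread of replicate spots and known shifts. Genes varied independently in these data, so they do not show how lists of co-varying genes behave. The work used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9, and R 4.3.3 with limma 3.58.1.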

Results

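Gene expression was measured in progenitor cells sorted from adult mouse bone marrow, on 4 single-colour Agilent arrays with 1 array for each of 4 groups. LSK cells (lineage-negative, c-kit high, Sca-1 positive) hold the haematopoietic stem cells and multipotent progenitors. The CLP sort (lineage-negative, c-kit low, Sca-1 low, IL7Rα positive) was gated to enrich for common lymphoid progenitors. Erythroid, basophil and myeloid progenitor genes were also much higher in it than in LSK, as given below. Differences in this sort need therefore not be those of lymphoid progenitors alone. Each sort came from wild-type (WT) littermates and from mice carrying an SFRP5 transgene. SFRP5 is a secreted antagonist of Wnt signalling, and the stated purpose of the series was to find genes regulated by its expression. Each array carried 55681 probes outside the controls. The share of probes well above background was 70.1% in WT LSK, 65.3% in SFRP5 LSK, 65.7% in WT CLP and 66.1% in SFRP5 CLP. Signals are given as log2 relative to the 75th percentile of their own array. With 1 array per group no value has a replicate check, no test between groups was made, and the number of arrays limits the precision of every difference. "Higher" and "lower" therefore describe these 4 arrays.

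The genes behind the sort gates, and Flt3, which was listed with them as a sort marker, differed between the sorts in both genotypes. Kit, the stem cell factor receptor, stood at 5.08 in WT LSK and 2.75 in WT CLP, and Ly6a, which encodes Sca-1, at 1.35 and -0.84. Il7r, the receptor chain that defines the lymphoid gate, stood at -0.51 in WT LSK and 2.52 in WT CLP. Flt3, a cytokine receptor of multipotent and lymphoid progenitors, was lower in CLP than in LSK, with log2 differences of -2.71 in WT and -2.78 in SFRP5. Over these 4 genes the median difference was -2.27 in WT and -1.72 in SFRP5, with Il7r alone higher in CLP. The array's only Sfrp5 probe had nearly the same level on all 4 arrays, -0.23 in WT LSK, -0.31 in SFRP5 LSK, -0.02 in WT CLP and -0.00 in SFRP5 CLP. Its difference between genotypes was -0.08 in LSK and 0.02 in CLP, and from -0.02 to 0.12 over the alternative settings in CLP, with a change of sign. Whether this mouse probe matches the transgene transcript is not given in the sources used here.

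Genes of the sex chromosomes separated the genotypes. Xist, the RNA that coats the inactive X chromosome of female cells, stood at 4.99 in SFRP5 LSK and 4.50 in SFRP5 CLP and was not above background on either WT array, so it was at least 880-fold higher in SFRP5 LSK and at least 606-fold higher in SFRP5 CLP. The Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty were above background on all 4 arrays and lower in SFRP5 than in WT. Their log2 differences in LSK were -1.35 for Ddx3y, -0.82 for Eif2s3y, -1.66 for Kdm5d and -1.54 for Uty. In CLP they were -1.52 for Ddx3y, -1.70 for Eif2s3y, -1.03 for Kdm5d and -2.26 for Uty, of which a further probe was below background on both SFRP5 arrays. Tsix, also sex-linked, went the other way to Xist, being above background on both WT arrays (-3.83 in LSK and -3.04 in CLP) and on neither SFRP5 array. The sex-linked list had medians of -1.43 in LSK and -1.56 in CLP, while its means were 0.79 and 0.53 because they take in Xist. Every difference between genotypes is therefore also a difference between arrays with unlike sex-linked expression.

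**Figure D1:**
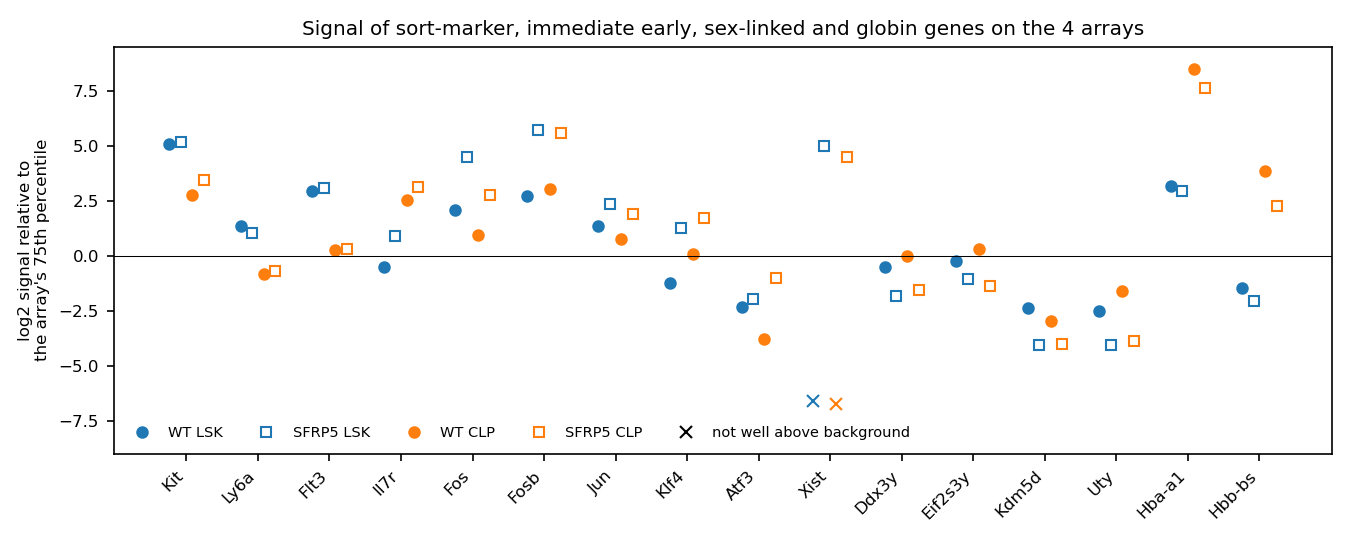
Log2 signal relative to each array's 75th percentile (vertical axis) for sort-marker, immediate early, sex-linked and globin genes, where each point is 1 gene on 1 of the 4 arrays (filled for WT, open for SFRP5, blue for LSK, orange for CLP, crosses for signals not well above background). Xist stands at 4.99 and 4.50 on the SFRP5 arrays and below background on the WT arrays, and Fosb at 5.74 and 5.57 on the SFRP5 arrays against 2.74 and 3.05 on the WT arrays.

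The comparison of SFRP5 with WT LSK cells asks which genes differ with the transgene in the stem and progenitor compartment. Immediate early genes, regulators that cells switch on quickly after a stimulus, were higher on the SFRP5 array. Of 23 measured, 11 were at least 2-fold higher, 0 at least 2-fold lower and 12 within 2-fold. Fosb, a partner in the AP-1 transcription factor, was 7.99-fold higher, and Klf4, a transcription factor of monocyte development, 5.65-fold higher. The lowest members were Gadd45b at -0.48 and Egr3 at -0.40. Fos, Dusp1 and Egr1, named here after their values were seen, had log2 differences of 2.41, 1.32 and 0.64. The median over the list was 0.82, at percentile 100 among random gene lists of the same size and signal level, and from 0.70 to 1.20 over the alternative settings.

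Genes that restrain the cell cycle and genes of myeloid progenitors were also higher in SFRP5 LSK. Of 25 cyclin-dependent kinase inhibitor and quiescence genes, 4 were at least 2-fold higher and 0 lower, led by Btg2 at 1.76 and Klf6 at 1.46, with Ndn lowest at -0.88. Both leading genes are also immediate early genes. The list median was 0.58 (percentile 100), and 0.38 (percentile 98.1) without the genes shared with the immediate early list. Of 23 granulocyte-monocyte progenitor genes, 5 were at least 2-fold higher and 1 lower, with a median of 0.57 (percentile 99.96), or 0.37 with background correction by normexp. Hp, the haemoglobin-binding plasma protein haptoglobin, was higher by 1.97 and Ms4a3, a marker of committed granulocyte-monocyte progenitors, was lower, at -2.33. Of 22 monocyte and macrophage genes, 4 were at least 2-fold higher and 2 lower (1 more lower by a bound), with F13a1 at 2.26 and Axl at -2.36. Their median was 0.55 (percentile 99.99), but inside the range of random lists with normexp (0.10, percentile 92.3) and over brighter genes alone (0.35, percentile 82.7). Mast cell, basophil and eosinophil genes had 9 of 17 members at least 2-fold higher and 0 lower, and 3 further members lower by a bound, with the mast cell protease Mcpt4 at 3.82. The median over that list was 0.35 (percentile 98.9), and it fell inside the range of random lists with normexp (0.16, percentile 96.4), without the filter on dim probes (0.10, percentile 97.1) and with the mean of a gene's probes (0.15, percentile 90.8). Mature neutrophil genes gave a median of 0.09 (percentile 91.3) that turned to -0.04 in the authors' deposited table and rose above the range of random lists with cyclic loess (0.51, percentile 98.8), with quantile normalization (0.50, percentile 98.6) and over brighter genes alone (0.93, percentile 98.99), with Ngp, a neutrophil granule protein, at 3.84 and Retnlg at -2.34.

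Some groups of growth and division genes were shifted upwards by small amounts in many members, while genes of the G1-S transition and replication (median 0.27, percentile 90.8) and MYC and ribosome biogenesis genes (0.04, percentile 12.5) were not shifted. All genes whose brighter array was at or above its 75th percentile had a median of 0.18 in this comparison. In bright lists, counts above 0 and raw medians therefore take in a shift common to bright genes. The percentiles compare a list with genes of the same level. Replication-dependent histone genes, which supply the nucleosomes of S phase, had 3 of 14 members at least 2-fold higher and 13 of 14 above 0, with H2ac18 at 1.29 and H2ac4 at 1.18. Their median was 0.82 (percentile 100). Mitosis genes had a median of 0.40 (percentile 99.92) with 42 of 50 above 0, and Anln, which encodes a protein of the contractile ring, was at 1.5. Of 73 ribosomal protein genes none reached 2-fold, yet 72 were above 0, with Rplp1 at 0.75 and Rps3 at -0.20. Their median was 0.32 (percentile 99.98) and ranged down to 0.09 with cyclic loess normalization. Respiratory chain genes had a median of 0.34 (percentile 99.2), with 49 of 52 above 0 and Cox7a2 at 0.87. That median was 0.16 with cyclic loess and lay inside the range of random lists with the mean of a gene's probes (0.31, percentile 95.4).

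Wnt genes, the pathway that the transgene product inhibits, lay inside the range of random lists in LSK in all 5 groups, though 2 of these moved above it under some alternative settings. Of 18 measured canonical Wnt target genes 1 was at least 2-fold higher, 0 lower and 17 within 2-fold, and 2 further members were higher by a bound, with Jun at 1.04, Met at 0.74, and Znrf3 and Tnfrsf19 both at -0.56. The list median of 0.0045 lay at percentile 55.3 and turned negative with cyclic loess (-0.07) and in the authors' table (-0.12), while the mean of the list was 0.32 (percentile 97.49). It was also negative over members above background on both arrays (-0.05, percentile 28.7) and over brighter genes alone (-0.02, percentile 14.7). The same held without the dim filter (-0.09), with the mean of a gene's probes (-0.10) and without the genes shared with the immediate early list (-0.05, percentile 52.1). Axin2, the most used read-out of the pathway and named here after its values were seen, was above background only in SFRP5 LSK and WT CLP, at -3.73 and -3.24. Wnt ligands and secreted antagonists had a median of -0.34 (percentile 13.8), with Wnt8b at -2.57 and Wls, the Wnt export receptor, at 0.59. Wnt receptors had a median of 0.25 (percentile 91.5), or 0.34 (percentile 97.8) with the mean of a gene's probes, with the receptor Fzd5 at 1.47 and Fzd6 at -1.35. Intracellular Wnt components had a median of 0.28 (percentile 95.3), which rose above the range of random lists with quantile normalization (0.38, percentile 99.9), cyclic loess (0.36, percentile 99.8) and a filter for signal on all 4 arrays (0.32, percentile 97.7), as did the mean of the list (0.30, percentile 97.6). The noncanonical branch had a median of 0.09 (percentile 48.3), or -0.04 in the authors' table, although Plcb1, a phospholipase that releases calcium, was at 3.16 and Prickle1, a planar cell polarity gene, at 1.94.

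Lymphoid and stem cell genes moved in both directions in LSK. Among 30 early lymphoid genes 7 were at least 2-fold higher and 3 lower, with the B cell adaptor Blnk at 2.04, Il7r at 1.40 and the homing receptor Ccr9 at -1.51 (list median 0.27, percentile 93.4). Among 35 stem cell genes 1 was at least 2-fold higher and 2 lower, with Hoxb5 at 1.37 and Mecom, a regulator of stem cell maintenance, at -1.82. Of 6 pre-B-cell receptor and immunoglobulin genes 3 were at least 2-fold higher and 1 lower, with the surrogate light chain genes Vpreb3 at 1.96, Vpreb1 at 1.44 and Igll1 at -1.36 (list median 1.03, percentile 99.8). Globin genes, whose near-identical copies leave the source of each probe's signal uncertain, had log2 differences of -0.19 for Hba-a1, -0.53 for Hba-a2, -0.59 for Hbb-bs, -0.63 for Hbb-b2 and -0.00 for Hbb-b1.

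Over all genes, 1059 of the 16126 above background on both LSK arrays were at least 2-fold higher in SFRP5 and 1159 were at least 2-fold lower, 13.8% in all. A further 229 were at least 2-fold higher and 554 at least 2-fold lower by a bound, being above background on 1 array alone. Among genes whose brighter array was at or above its 75th percentile, the highest were Bglap (osteocalcin, 15.9-fold; its near-identical paralogs leave the source of the signal uncertain), Ngp (14.4-fold), Bdh1 (12.6-fold), Insl6 (10.3-fold), Mt2 (a metallothionein, 8.53-fold) and Fosb. Ear1, an eosinophil ribonuclease with close paralogs, followed at 2.78, Zfp503 at 2.89, Acbd4 at 2.68 and Dclk2 at 2.92, of which Dclk2 fell to -0.01 with the mean of its probes. In WT and in SFRP5, Mt2 (6.60 and 2.46) and Ear1 (6.63 and 3.76) were higher in CLP than in LSK. Ngp (4.35 and -1.01) and Bdh1 (4.19 and -0.00) were higher in WT CLP alone, and Bglap, Insl6 and Zfp503 lower in both genotypes. Each such value shares an array with the genotype difference. Whether the make-up of the SFRP5 LSK sort differed was not tested. Under the same limit the lowest were Hira (a histone chaperone, 48.5-fold lower), Gimap4 (a GTPase of lymphocyte survival, 21.0-fold lower) and Tead2 (a Hippo pathway transcription factor, 8.19-fold lower). Arhgap35 at -2.72, Zfp219 at -2.72, Kazald1 at -2.62, Kcnq1ot1 at -2.50, Tcp11 at -2.50, Zranb3 at -2.33 and Zfp397 at -2.30 completed them. A further probe of the same gene gave -2.74 for Tead2 and -1.89 for Gimap4 but 0.14 for Hira, 0.62 for Zfp219, 0.90 for Tcp11, 1.24 for Zranb3 -0.20 for Zfp397 and -0.63 for Zfp503, and Zfp219 changed sign with normexp (0.45). By bounds, Vmn1r225 (28.6-fold), Epha2 (20.5-fold), Plg and Pla1a (both 20.2-fold) were at least that much higher, and Angptl1 (24.9-fold), Mia (21.0-fold), Fut1 (19.7-fold), Plekhg6 (16.7-fold) and Zfp777 (16.1-fold) at least that much lower. The share of the 2-fold genes that was higher, 47.8%, became 59.0% with quantile normalization, 63.3% with cyclic loess, 62.6% with normexp and 33.4% in the authors' table, whose scaling moves the median of all genes by -0.13. For the 490 of these genes with a further probe above background, that probe pointed the same way in 63.5% and also reached 2-fold in 24.1%. Unrelated probes would point the same way about as often as not. Across all 4457 genes with a further probe, the differences of the main and further probes had a Pearson r of 0.19. Most of these single-gene differences were thus weakly repeated by another probe.

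The same comparison was made in the CLP sort. Immediate early genes were again higher on the SFRP5 array, with 10 of 23 at least 2-fold higher, 1 lower and 12 within 2-fold. Atf3, a stress-induced transcription factor, was 6.79-fold higher, Fosb 5.77-fold, Klf2 4.37-fold and Jun 2.19-fold, while Egr2 was at -1.07 and Egr3 at -0.65. Fos, named after its values were seen, was at 1.84. The list median was 0.88 (percentile 100), and from 0.86 to 1.08 over the alternative settings. Of 25 cyclin-dependent kinase inhibitor and quiescence genes 4 were at least 2-fold higher and 0 lower (median 0.35, percentile 100), and their median was 0.27 (percentile 99.7) without the genes shared with the immediate early list.

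B lineage, early lymphoid and T lineage genes were higher by small amounts in SFRP5 CLP, and so were granulocyte-monocyte progenitor genes (median 0.15, percentile 99.2, with 1 of 25 at least 2-fold higher and 0 lower). The value of that last list ran from 0.13 to 0.34 over the settings. Natural killer and innate lymphoid genes (-0.13, percentile 24.1) were not shifted, and pre-B-cell receptor and immunoglobulin genes (0.20, percentile 93.3) rose above the range of random lists with quantile normalization alone (0.38, percentile 98.5). Of 31 B lineage genes 4 were at least 2-fold higher and 0 lower, with 26 above 0 and a median of 0.27 (percentile 99.98). Rag1, a recombinase of antigen receptor genes, was higher by 1.33 and Spib, a lymphoid transcription factor, by 1.36, and Ly6d, which marks B cell fate within CLP, was at -0.65. Early lymphoid genes had 2 of 31 at least 2-fold higher and 2 lower, with the homing receptor Ccr7 at -1.94 (list median 0.31, percentile 99.98). That list fell inside the range of random lists with the mean of a gene's probes (0.13, percentile 95.4) and with the mean of the list (0.15, percentile 93.8). T lineage genes had a median of 0.39 (percentile 99.5), with the kinase Zap70 at 1.05, but lay inside the range of random lists with the mean of a gene's probes (0.02, percentile 62.9), with the mean of the list (0.09, percentile 66.6), without the filter on dim probes (0.13, percentile 89.0) and over brighter genes alone (0.25, percentile 89.7). Chromatin regulators of the Polycomb and Trithorax groups had a median of 0.32 (percentile 100), with 20 of 28 above 0. The X-linked Kdm6a, a histone demethylase, was at 1.47 and Kdm6b at 1.05.

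Erythroid genes and genes of protein synthesis, respiration and replication were lower in SFRP5 CLP. Of 27 erythroid genes 1 was at least 2-fold higher (1 more by a bound) and 2 lower, but 25 were below 0, with a median of -0.52 (percentile 0). The value of the erythroid list ran from -0.59 to -0.31 over the settings. The 6 globin genes above background on both arrays were all below 0, as were 7 of 8 with those above it on 1 array alone, with the paralogs Hbb-bs at -1.60, Hba-a1 at -0.88, Hbb-b2 at -0.86, Hbb-b1 at -0.86, Hba-a2 at -0.61 and Hba-x at -0.45. Beside them, 72 of 73 ribosomal protein genes were below 0, with Rps27 at -0.97 and Rps3 at 0.19 (list median -0.42, percentile 0), and that median was -0.21 with quantile normalization. Respiratory chain genes had 47 of 52 below 0, with Ndufs8 at -0.87 (median -0.31, percentile 0), and -0.19 with quantile normalization. Histone genes had 2 of 14 at least 2-fold lower, with H2bc3 and H1f1 both at -1.01 (median -0.57, percentile 0). Genes of the G1-S transition and replication had a median of -0.21 (percentile 0.98), with Ccne1 at -0.84, and with quantile normalization this list lay inside the range of random lists (-0.06, percentile 4.16).

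The Wnt groups were each set against random lists in CLP too, and were not compared with one another. Noncanonical Wnt components had 6 of 30 at least 2-fold higher and 1 lower, with Prkca, a protein kinase C, at 1.84 and Plcb1 at 1.61 (median 0.34, percentile 100). Intracellular components of the canonical pathway had a median of 0.30 (percentile 100), with Bcl9, a coactivator of beta-catenin, at 1.30 and Ctnnbip1, which blocks beta-catenin, at 1.07, but a median of 0.04 (percentile 80.3) with the mean of a gene's probes. Canonical target genes had 1 of 19 at least 2-fold higher, 1 lower and 17 within 2-fold, and 2 further members lower by a bound, with Jun at 1.13, Lef1 at 0.77, Ccnd1 at -0.99 and Znrf3 at -1.12. Their median of 0.06 lay at percentile 81.7 and turned to -0.05 with normexp, and their mean was -0.18. With members above background on both arrays alone the median was 0.22 (percentile 98.9), above the range of random lists, as it was with a filter for signal on all 4 arrays (0.19, percentile 97.6). Rnf43, a target gene that limits Wnt receptors, was at least 16.2-fold lower, being above background only in WT CLP. Wnt receptors had a median of -0.08 (percentile 39.3) that turned positive in the authors' table, with Fzd6 at 1.69, and the ligands 0.02 (percentile 62.5), which turned negative with normexp and with median scaling, with Wnt5b at -1.40.

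Over all genes, 679 of the 15942 above background on both CLP arrays were at least 2-fold higher in SFRP5 and 686 at least 2-fold lower, 8.56% in all, with a further 274 higher and 282 lower by a bound. Among genes whose brighter array was at or above its 75th percentile, the highest were Phc1 (a Polycomb subunit, 29.8-fold), Als2cl at 3.25, Aldh5a1 at 3.01, Klhl1 at 2.65, Rab2b at 2.61, Fosb, Cdon at 2.51, Plekha7 at 2.38, Esrra at 2.26 and Ddc at 2.17. A further probe gave 0.54 for Phc1, 0.53 for Ddc and -2.34 for Plekha7. Under the same limit the lowest were Adam33 at -2.58, Perp (a p53 target in cell adhesion, 5.66-fold lower), Mogat2 at -2.15, Lynx1 at -2.11, Camp (an antimicrobial peptide of neutrophils, 4.12-fold lower), Dhx34 at -1.98, Sesn2 at -1.90, Pramel12 at -1.74, Zfp41 at -1.71 and the Y-linked Eif2s3y, with a further probe at 1.41 for Dhx34 and 0.35 for Lynx1. By bounds, Syde1 (26.2-fold), Izumo3 (21.5-fold), Cep112 (19.5-fold) and Procr, a surface marker of stem cells (18.3-fold), were at least that much higher, and Gsg1 (12.5-fold), Nol3 (12.4-fold), Bco2 (11.4-fold) and Eid2b (9.43-fold) at least that much lower. Hlf, a transcription factor of stem cells, was higher by 3.71, and the stem cell list had 4 of 29 at least 2-fold higher and 0 lower, and 3 further members higher by a bound. Its median of 0.15 (percentile 95.5) depended on the setting, being 0.23 (percentile 98.2) with quantile normalization, 0.02 with a filter for signal on all 4 arrays and -0.18 (percentile 12.7) over brighter genes alone, and its mean was 0.54 (percentile 99.99). The share of the 2-fold genes that was higher, 49.7%, became 60.1% in the authors' table. A further probe pointed the same way for 64.9% of 282 such genes and also reached 2-fold for 20.2%. Across all 4378 genes with a further probe, the main and further probes had a Pearson r of 0.22.

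**Figure D2:**
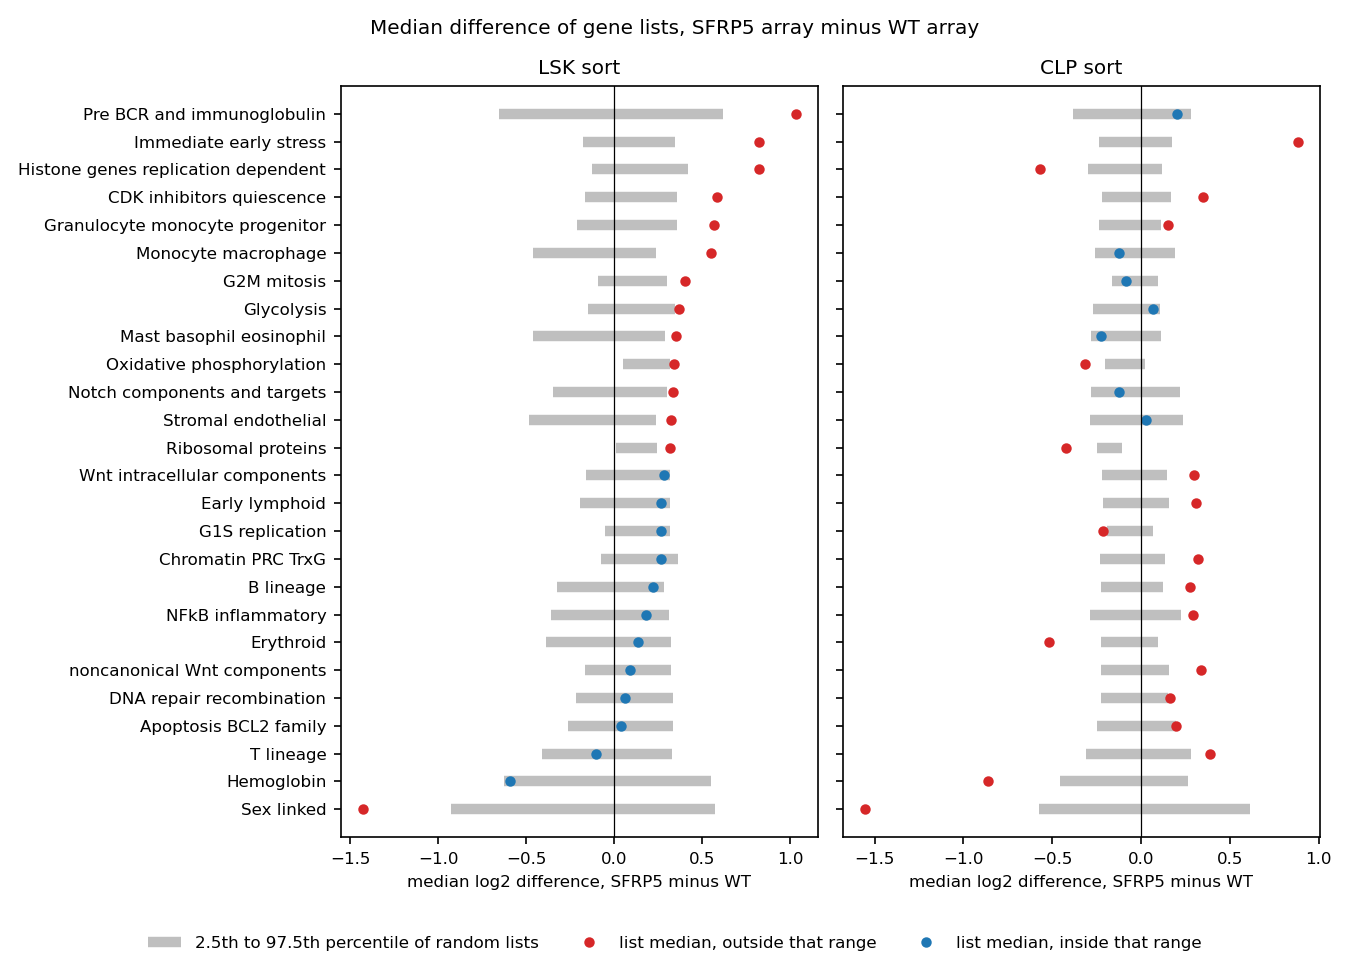
Median log2 difference, SFRP5 minus WT, of the members of each gene list (horizontal axis) in LSK and in CLP, for the 26 lists that lie outside the middle 95% of matched random lists (grey bars) in at least 1 sort, where each point is 1 list, red outside and blue inside that range. Immediate early genes lie at 0.82 and 0.88, while ribosomal protein genes lie at 0.32 in LSK and -0.42 in CLP.

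The genotype differences of the 2 sorts, which share no array, were then set side by side to find genes shifted in both. Fosb (3.0 in LSK and 2.53 in CLP), Pde8a (2.35 and 2.69), Plekha7 (2.17 and 2.38) and Bglap (3.99 and 1.98) were among the highest in both. Tubb1, a platelet tubulin (-2.84 and -2.08), Has3, a hyaluronan synthase (-2.69 and -1.96), Tnk1 (-1.77 and -2.30), Dpf3 (-1.74 and -2.96) and Abcb9 (-1.68 and -2.40) were the lowest. A further probe went the other way in both sorts for Tnk1 (0.47 and 1.64), in LSK for Pde8a (-0.43, and 0.37 in CLP) and in CLP for Plekha7 (1.68 in LSK and -2.34), and gave -0.24 for Dpf3 in CLP. With the mean of a gene's probes Tnk1 was at -0.65 and -0.33, Pde8a at 0.96 and 1.53 and Plekha7 in CLP at 0.02, and with normexp Dpf3 in LSK was at -0.34, Tubb1 in CLP at -0.84 and Has3 in CLP at -0.99. Among 15181 genes above background on all 4 arrays, 85 were at least 2-fold higher in both sorts against 38.0 if the sorts were independent, 88 were lower in both against 40.2, and 207 were 2-fold in opposite directions against 78.2. As opposite calls were in excess too, the excess in the same direction does not by itself show a shared genotype difference. Across genes, which are not independent replicates, the differences had a Pearson r of -0.05 and a Spearman rho of -0.07. The sorts differed by at least 2-fold in their genotype difference for 3438 genes. Among these, Phc1 (5.75), Tead2 (5.66), Trib3, a stress-induced pseudokinase (5.53), Hira (5.28) and Tlnrd1 (4.96) had the highest CLP minus LSK values, and Ngp (-5.36), Zfp503 (-4.25), Bdh1 (-4.19) and Mt2 (-4.13) were among the lowest.

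**Figure D3:**
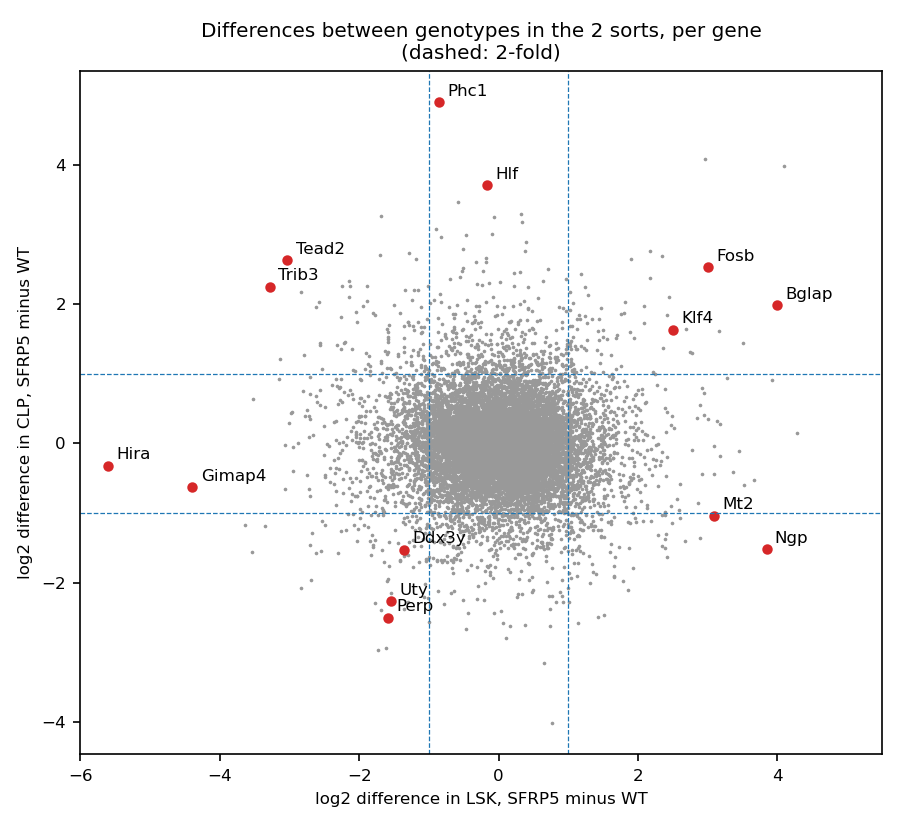
Log2 difference between SFRP5 and WT in LSK (horizontal axis) against the same difference in CLP (vertical axis), where each grey point is 1 of 15181 genes above background on all 4 arrays, red points are genes named in the text and dashed lines mark 2-fold. The cloud has a Pearson r of -0.05 across genes, with Fosb at 3.0 and 2.53 and Hira at -5.60 and -0.32.

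The comparison of CLP with LSK cells shows what separates the sorts in each genotype. Erythroid genes were among the groups with the highest medians, with 21 of 24 measured at least 2-fold higher in CLP and 0 lower (median 5.04, percentile 100), and 21 of 23 in SFRP5 (3.74, percentile 100). Rhag, a red cell membrane protein, was 132-fold higher in WT CLP and 107-fold in SFRP5 CLP, and Hba-a1, with close paralogs, was 40.7-fold and 25.2-fold higher. Basophil, mast cell and eosinophil genes were higher too, with 13 of 20 in WT and 14 of 17 in SFRP5 at least 2-fold higher, among them Prss34, a basophil protease (6.40 and 5.75), and Ear6, which has close paralogs (7.47 and 5.81). Their medians were 4.18 and 3.76, or 1.36 and 1.84 with normexp, and 6.14 in WT with a filter for signal on all 4 arrays. Granulocyte-monocyte progenitor genes had medians of 2.07 and 1.91, with Elane, neutrophil elastase, at 5.97 and 4.60.

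B lineage genes were higher in CLP, with 17 of 26 in WT and 18 of 25 in SFRP5 at least 2-fold higher and 0 lower in either (medians 2.85 and 2.84, percentile 100 in both; 1.65 in WT with normexp). Igll1 was at 5.24 and 6.71, Vpreb1 at 5.18 and 3.94, Rag1 at 2.71 and 4.26, and Ly6d at 3.29 and 3.66. Early lymphoid genes split, with 10 at least 2-fold higher and 12 lower in WT, and 9 and 11 in SFRP5, and their median near 0 changed sign between scalings. Genes of cell division were higher, with 44 of 51 mitosis genes in WT and 23 of 50 in SFRP5 at least 2-fold higher (medians 1.47 and 0.94), and respiratory chain genes had medians of 1.44 and 0.79, the former 0.94 with quantile normalization. Ribosomal protein genes had a median of 0.83 (percentile 99.98) in WT, or 0.19 with cyclic loess, and of 0.09 (percentile 74.8) in SFRP5, where cyclic loess, quantile normalization and the authors' table turn it negative.

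Stem cell genes were lower in CLP, with 17 of 29 in WT and 17 of 33 in SFRP5 at least 2-fold lower (medians -1.64 and -1.18, percentile 0 in both; -2.07 in SFRP5 over the brighter genes alone). Hlf was at -9.0 and -5.13 and Meis1, a partner of Hox proteins, at -3.51 and -3.41. Hox cluster genes had medians of -2.47 and -1.94, but of -0.96 and -0.88 with normexp and of -0.23 and -0.38 without the filter on dim probes, where the list in WT lay inside the range of random lists (percentile 7.32). Interferon response genes had 15 of 39 in WT and 17 of 38 in SFRP5 at least 2-fold lower, with Oasl2 at -5.11 and -4.34 (medians -0.80 and -0.93; -1.22 in WT in the authors' table). Immediate early genes were lower in CLP, with 8 of 23 at least 2-fold lower in each genotype (medians -0.55 and -0.53; -0.96 in WT in the authors' table), Nr4a1 being at -3.37 and -2.56. Canonical Wnt target genes were lower in SFRP5 CLP, with 5 of 17 at least 2-fold lower and Mycn at -4.03 (median -0.41, percentile 0.25), although the mean of the list, -0.13, lay inside the range of random lists. In WT their median of -0.25 (percentile 19.1) turned positive with normexp and quantile normalization, and their mean was 0.37, with Mycn at -4.74.

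Over all genes, 2847 of 16016 in WT and 1807 of 15710 in SFRP5 were at least 2-fold higher in CLP, and 2291 and 1729 at least 2-fold lower, that is 32.1% and 22.5%. Besides those above, Ahsp (7.47 and 6.43), Kel (6.32 and 7.08), Rhd (6.31 and 6.32), Acp5 (6.31 and 5.68), Sec14l2 (5.61 and 6.28), Paqr9 (7.90 and 5.60) and Slc38a5 (5.68 and 5.60) were the highest in both genotypes. The paralogs Ctla2a (-4.49 and -4.83) and Ctla2b (-4.39 and -5.00), Pear1 (-4.37 and -5.01), Nfatc2 (-5.30 and -3.99), Adgrl4 (-3.92 and -4.28) and Epb41l3 (-3.82 and -4.20) were among the lowest, with a further probe at -1.27 and -1.52 for Pear1 and -1.01 and -1.19 for Nfatc2. The differences of the 2 genotypes had a Pearson r of 0.63 and a Spearman rho of 0.55 across 15181 genes, with 1063 genes higher in both against 316 if independent, 806 lower in both against 228, and 132 opposite against 539. The share of the 2-fold genes that was higher, 55.4% in WT and 51.1% in SFRP5, became 66.0% in WT with normexp, and 26.6% and 37.6% in the authors' table, whose scaling moves the median of all genes by -0.41 and -0.19. Median scaling moves it by 0.11 in WT. A further probe pointed the same way for 86.2% of 1326 2-fold genes in WT and 79.8% of 916 in SFRP5. Across all genes with a further probe, the main and further probes had a Pearson r of 0.60 in WT and 0.50 in SFRP5.

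**Figure D4:**
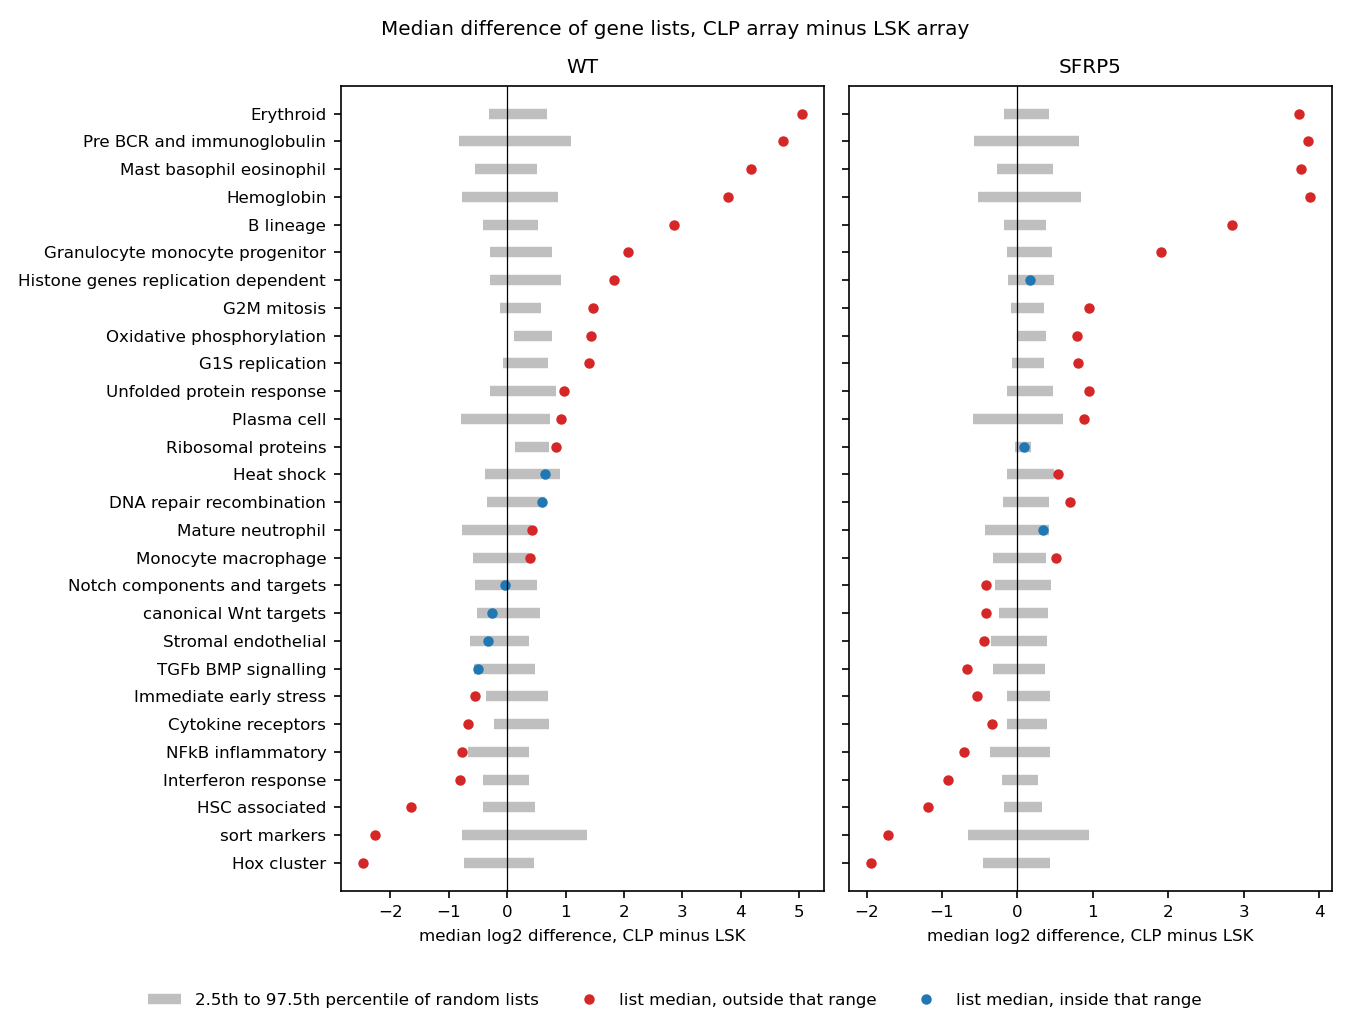
Median log2 difference, CLP minus LSK, of the members of each gene list (horizontal axis) in WT and in SFRP5, for the 28 lists outside the middle 95% of matched random lists (grey bars) in at least 1 genotype, where each point is 1 list, red outside and blue inside that range. Erythroid genes lie at 5.04 and 3.74 and stem cell genes at -1.64 and -1.18.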

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

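The tests of explanations in this part were chosen only after the result was seen, except those of the immediate early and ribosomal lists with cyclic loess normalization, which were written before.

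Among gene lists, the genotype difference went opposite ways in the 2 sorts for 3 lists, each outside the range of random lists in both sorts. With 1 array per group the difference between sorts was not tested here or in any of the cases that follow. Replication-dependent histone genes had medians of 0.82 in LSK and -0.57 in CLP, which are -1.39 apart. Ribosomal protein genes had medians of 0.32 and -0.42 (-0.74 apart), and respiratory chain genes 0.34 and -0.31 (-0.66 apart). Among single genes, those chosen for the largest differences between sorts that were also at least 2-fold in opposite directions were Tead2 (-3.03 in LSK and 2.63 in CLP, 5.66 apart), Trib3 (-3.28 and 2.25, 5.53 apart) and Tlnrd1 (-1.69 and 3.26, 4.96 apart). In the other direction they were Ngp (3.84 and -1.52, -5.36 apart), Zfp503 (2.89 and -1.36, -4.25 apart) and Mt2 (3.09 and -1.04, -4.13 apart). A further probe gave the reverse for Zfp503 (-0.63 and 0.61), and -2.74 and 0.45 for Tead2. With normexp Trib3 in CLP (0.71), Tlnrd1 in LSK (-0.69) and Zfp503 in CLP (-0.52) fell under 2-fold, as did Mt2 in CLP with quantile normalization (-0.90).

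Xist was present on both SFRP5 arrays and on neither WT array. On a swap of labels between genotypes within 1 sort, 0 arrays had an Xist call unlike that of the other array of their genotype. That count restates the pattern seen, so it is no separate test of a swap. A swap in both sorts would look the same as none. A different sex make-up of the mice is a candidate explanation, since 8 of 8 Y-linked differences were below 0. Because the Y-linked genes stayed above background on the SFRP5 arrays, a mixture of female and male cells may underlie them. A mixture alone would lower the 2 Uty probes alike, but in LSK they fell from -2.52 to -4.06 and from -1.25 to -4.46. The last is below background, and signals this dim do not decide. Whether the remaining signal comes from Y-linked transcripts was not tested, so the mixture stays a hypothesis. Genes that escape X inactivation had percentiles of 99.5 in LSK and 96.3 in CLP, so whether they follow the sex make-up cannot be told apart from chance in CLP, and neither can an effect of the transgene from one of sex for any other gene.

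Immediate early genes were higher on the SFRP5 array in both sorts. The list stayed at percentiles 100 and 100 after cyclic loess. The random lists are already matched on signal level, so cyclic loess could hardly move it and adds little. The list's place at percentile 100 among genes of the same level argues against a trend with signal alone. A handling response that takes in heat shock genes stays open, since their list lay at percentiles 44.0 in LSK and 51.7 in CLP with members that went both ways, Hspa1a being at 0.64 and 2.34. More neutrophils or monocytes stay open in CLP (list medians -0.21 and -0.13, over members that went both ways) and in LSK (0.087 and 0.55), although the lineage gate should remove them. Genotype, sex make-up and order of isolation likewise stay open, since each coincides with the groups or is not recorded.

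Ribosomal protein and respiratory chain genes were higher on the SFRP5 array in LSK and lower in CLP. After cyclic loess the ribosomal list lay at percentiles 99.99 and 0.0 and the respiratory chain list at 98.7 and 0.0. As the random lists are matched on signal level, cyclic loess could hardly change that result. The distance from genes of the same level argues against a signal-dependent distortion as the whole cause. Such a distortion may account for part, because the medians shrank to 0.09 and -0.24 for ribosomal and to 0.16 and -0.23 for respiratory chain genes. An equal shift of abundant genes through amplification or RNA quality cannot be told apart, since housekeeping genes had medians of 0.27 in LSK and -0.03 in CLP, with an SD of 0.40 and 0.32 between members. In CLP, fewer erythroid cells on the SFRP5 side are a candidate explanation, with medians of -0.86 for haemoglobin (7 of 8 genes lower) and -0.52 for erythroid genes, although the lineage gate should remove mature erythroid cells. In LSK the haemoglobin genes went against more cells rich in haemoglobin, with 7 of 7 lower (median -0.59, percentile 3.16, SD between members 0.33). This is weak, since near-identical copies are not independent and the median lay inside the range of random lists. Erythroid cells with little haemoglobin stay open (erythroid list median 0.13, percentile 79.9), and an effect of genotype is untested.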

How the results depend on the processing

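The settings chosen only after the data were seen are the restrictions to brighter genes and to list members above background on both arrays, and the lists without immediate early genes. No paired analysis was made, because each group holds 1 sample and the fit of genotype plus sort was not run. Signal over background limits low-signal genes most, where replicate spots spread more. Leaving out saturated probes changed nothing, as no spot was saturated. Of single-gene differences under the alternatives, 868 moved by less than the spread of replicate spots, 215 by more and 2 turned from a 2-fold difference to the other sign. Filters cannot change a gene's difference, and they gave 110 (signal on all 4 arrays), 111 (no dim filter) and 87 (brighter genes alone) of the 868. Leaving out saturated probes gave 111 more. With normexp 102 moved by more and 1 turned. The normexp offset, added to every spot, shrinks the folds of dim genes by design. Counting differences of any size, with those fixed values among them, 5 of 1085 had the other sign, in 4 of 111 results, and so had 192 of 2506 list values, in 71 of 192 results. Of list results 2353 kept their side of the random range, 89 moved out of it, 61 moved into it and 3 went to the other side of the median of the random lists. Median scaling and the authors' factor per array shift all genes alike, and no spot was saturated. A list's place among random lists could hardly change under these settings. They gave 192 (median scaling), 191 (authors' table) and 192 (saturated probes left out) of the 2353. Of counts, 77 stayed within 1.5 times and 55 did not, and of correlations 7 stayed and 3 moved. The immediate early list stayed above the range in both sorts and the ribosomal list outside it on opposite sides, under all list settings run. Among these settings, those that shift all genes alike or change no spot could hardly have moved them.

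With a 1.5-fold threshold, genes higher and lower were 2731 and 2899 for genotype in LSK, 1801 and 2034 in CLP, 4745 and 4244 between sorts in WT, and 3552 and 3009 in SFRP5, with 346 higher and 406 lower in both sorts and 7063 apart between sorts. With a 3-fold threshold they were 293 and 373, 218 and 168, 1157 and 929, and 753 and 823, with 19 and 11 in both and 1242 apart. Both follow from the threshold itself. Without the filter on dim probes they were 1780 and 3180, 1687 and 2035, and 3201 and 3076 in SFRP5, with 4251 lower in WT, 214 and 500 in both and 7352 apart, with more genes counted. With normexp they were 467 and 279, 170 and 156, and 1076 and 1010 in SFRP5, with 1040 lower in WT, 28 and 7 in both and 1635 apart. Over brighter genes alone they were 498 and 262, 187 and 158, and 1142 and 831 in SFRP5, with 996 lower in WT, 48 and 18 in both and 1700 apart, with fewer genes counted. In the authors' table, genes between sorts in WT were 1537 higher and 4240 lower. With cyclic loess 55 genes were lower in both sorts. The correlation of the genotype differences was -0.00036 without the filter on dim probes, -0.013 with normexp and -0.064 with quantile normalization. The counts in the authors' table follow from its factor per array, which moves the median of all genes between sorts in WT by -0.41. Normexp added an offset of 50 to every spot, against median processed signals from 31.19 in WT CLP to 49.27 in WT LSK. Such an offset shrinks the folds of dim genes by design, so the lower counts with normexp follow at least in part from it. What background correction itself added was not tested, nor was the cause for cyclic loess or the correlations.

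Canonical Wnt targets in CLP moved above the range of random lists with a filter for signal on all 4 arrays (0.19, percentile 97.6), with members above background on both arrays (0.22, percentile 98.9) and over brighter genes alone (0.28, percentile 98.8), each of which drops dim members. Respiratory chain genes in LSK moved into the range with the mean of a gene's probes (0.31, percentile 95.4), cause not tested. Among differences of at least 2-fold and lists outside the random range, those that changed sign, or side of the random lists' median, were Dclk2 in LSK with the mean of its probes (-0.0097), Zfp219 in LSK with normexp (0.45), plasma cell genes between sorts in WT over brighter genes alone (0.23, percentile 49.4, so inside the range), NF-kB targets in CLP with normexp (-0.03, percentile 87.5), monocyte and macrophage genes between sorts in WT in the authors' table (-0.02, percentile 98.1, still above the range), and sex-linked genes with the mean of the list (0.79 in LSK and 0.53 in CLP), which takes in Xist. The change of sign in the authors' table follows from its factor per array. For the others but the sex-linked genes the cause was not tested. The brightest probe of a gene was chosen again under each setting. With normexp another probe may therefore stand for Zfp219, of which a further probe was at 0.62 in LSK in the main setting. Below 2-fold, Bdh1 in CLP changed sign with the mean of its probes (0.17), and the Sfrp5 probe in CLP with normexp (-0.02) and with median scaling (-0.0029).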

Other observations

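Other gene groups were described after the values were seen or lie outside the main comparisons. Interferon response genes, MYC and ribosome biogenesis genes and unfolded protein response genes lay inside the range of random lists between genotypes in both sorts, although the mean of the unfolded protein response list in CLP (0.33, percentile 99.99) lay above it. Interferon genes had medians of 0.11 in LSK and -0.01 in CLP, which change sign between scalings. Unfolded protein response genes were higher in CLP than in LSK, with 10 of 21 at least 2-fold higher and 3 lower in WT (median 0.98) and 8 and 0 in SFRP5 (median 0.94), Asns, an amino acid synthase, being at 3.80 and 3.87. Notch genes had a median of 0.34 in SFRP5 LSK against WT (percentile 98.7), with the ligand Jag2 at 3.14 and the target Hey1 at 2.22, but 0.25 (percentile 93.6) with cyclic loess, 0.26 (percentile 93.7) with quantile normalization and 0.37 (percentile 88.4) over brighter genes alone. Stromal and endothelial genes had a median of 0.33 (percentile 99.3) in the same comparison, with Col1a2 at 1.51 and Cxcl12 at -1.41, but 0.04 (percentile 69.7) over members above background on both arrays. Glycolysis genes had a median of 0.37 (percentile 98.3), with Pfkfb4 at 2.12, but lay inside the range of random lists with the mean of a gene's probes (0.36, percentile 97.4) and over brighter genes alone (0.37, percentile 96.3). In CLP, inflammatory NF-kB targets had a median of 0.29 (percentile 99.1), with Zfp36 at 1.79 and Tnf at -1.45, but -0.03 with normexp and 0.18 (percentile 93.7) without the immediate early genes. TGF-beta and BMP genes were lower in SFRP5 CLP than in SFRP5 LSK (median -0.66, percentile 0.03).

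KEGG pathways of the array annotation were examined only after the data were seen. In LSK 46 of 218 pathways lay above and 6 below the range of random lists, against 10.9 outside it if members varied independently, with overlapping members. Genes of the pentose phosphate pathway had a median difference of 0.51 (24 genes), pyruvate metabolism 0.41 (37 genes) and adherens junctions 0.39 (66 genes), and retinol metabolism was lowest at -0.57 (36 genes). In CLP 16 of 217 lay above and 11 below, against 10.8 on the same assumption. Porphyrin metabolism, the route to haem, was lowest at -0.55 (23 genes), followed by the ribosome at -0.42, while B cell receptor signalling was at 0.18 (74 genes) and primary immunodeficiency genes at 0.27 (29 genes).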
